A study of Zostera marina with 23 samples.

How the data were processed

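Total RNA of 23 eelgrass samples was enriched for messenger RNA with oligo(dT) beads and sequenced as paired ends on an Illumina HiSeq instrument, per the labels' protocols. The submitters' processing notes name TopHat2 2.0.12, Cuffnorm 2.2.1 and Cuffdiff 2.2.1, without saying in which role or order. The genome build, the annotation and the use of strand are not given in the sources used here. Reads shared between near-identical genes may be counted at each copy or divided between them, which leaves the values of such genes uncertain.

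The table that the authors deposited as counts holds a scaled signal, a fragment count per gene multiplied by 1 factor per library. In each library 99.6% to 99.8% of the non-zero values lay within 0.01 of a whole multiple of 1 step, which ranged from 0.524 to 4.52, and 0.286% of all non-zero values did not. The values are called scaled fragments here. A second table deposited by the authors holds FPKM, in which fragments are divided by gene length and library total, and was used only as an alternative. Because some values, among them residues close to 0, were not whole, the count-based tests planned as alternatives were not run. The step, which was read from the values, served to estimate depth, floors and counted fragments. These entered the counting intervals, the chi-square between replicates, total-fragment scaling and the check for whole multiples, but not the reported limma fits. Depth was 5696800 to 13679082 fragments per library. Genes with at least 3 fragments numbered 13644 to 16480 per library. A group at 0 was given a floor of 3 fragments per library, and floors and counting intervals cover counting error only. Of 22733 identifiers, 2936 were at 0 in every library.

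The groups came from the titles. The library whose title says early and whose tissue label says late was left unassigned, and 22 libraries were compared. No libraries of a group agreed within sampling noise: the smallest chi-square per degree of freedom between replicates was 18.8, for male replicates 3 and 4. The labels give no batch.

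Genes with a value of at least 10 in at least 2 libraries were tested, 17423 in all. Log2(value + 1) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust settings) as 1 model with a coefficient for each of the 5 groups, and the female flower was the mean of the early and the late coefficient. The deposited scaling was kept. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. Tissue-enriched genes were at least 4-fold above each other tissue at an adjusted p under 0.05. Shares of fragments in such genes were measured with sets made again without the library measured, and the share within a given set does not depend on the library factors, although the set itself does. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the tables, checks and plots.

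The genes named are, for each comparison and direction, the 2 called identifiers with the largest fold among those whose libraries of 1 group all lie above those of the other and whose higher group has a mean of at least 100. This rule, the groups, the tests and the alternatives were fixed before the data were examined, except for the alternatives said to be chosen afterwards. The rule had asked for genes with product names and for lists of genes defined by product names. No table of names was given and the files hold identifiers alone, so those lists were not analysed here. The steps were tested on simulated data made from these libraries, with 200 genes changed by known folds. These 200 genes were drawn from the more abundant ones and divided among the folds. No library was simulated as lying apart, so recovery was not shown for genes of low values or for such libraries. Numbers in parentheses are the genes tested. Of the genes changed 4-fold, 77.6% were recovered for root against leaf (16938 genes), 80.6% for female flower against leaf (16945), 76.1% for male flower against leaf (16959), 83.6% for male against female flower (16953) and 58.2% for late against early female flower (16924). Of the genes changed 2-fold, the test recovered 26.9%, 25.4%, 38.8%, 29.9% and 16.4% in the same order. Most changes of that size would be missed, in part because a call required an estimated change of at least 2-fold. In the simulation each unchanged gene had the same mean and spread in all groups, unlike the real tissues. In the real fit the median standard error for late against early female flower was 0.750 in log2. The 58.2% therefore does not show that 4-fold changes between these stages would be found there.

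Alternatives were other pseudocounts, filters and scalings, the FPKM table, library weights, fits of the compared groups alone, the replicate number as a block, each replicate left out in turn, and both placements of the unassigned library. Scaling to equal total fragments and leaving out libraries that lay apart were added after seeing the data.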

Results

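Messenger RNA of eelgrass, Zostera marina, a flowering plant that grows, flowers and sets seed submerged in seawater, was measured by paired-end RNA sequencing in 4 tissues. The plants were brought from winter field conditions into tanks, where the water was warmed from 5 to 15 °C and the light period was lengthened from 12 to 16 hours to induce flowering. The series held 23 libraries. The female flower was sampled at an early time point (n = 3) and a late time point (n = 2) of its development, beside male flower (n = 7), root (n = 4) and leaf (n = 6). A further library had a title that called it early and a tissue label that called it late, so it entered no comparison. The labels do not say that the replicates came from separate plants, so p-values measure the spread between these samples, which may be partly technical. Total depth was 5696800 to 13679082 fragments per library over 22733 gene identifiers. The files pair the identifiers with no gene names, so genes are given by identifier, at most 2 that rose and 2 that fell in each comparison, and gene groups are defined by the tissue in which the genes were highest.

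Tissue separated the libraries. The first 3 principal components of log2(scaled fragments + 1) held 41.0%, 24.5% and 14.4% of the variance. Across genes, which are not independent replicates, the median Pearson correlation between libraries of the same group was 0.911 for male flower, 0.890 for root, 0.893 for leaf and 0.960 for early female flower, and the 2 late female libraries correlated at 0.968. Early and late female libraries correlated with each other at a median of 0.932. Male flower stood farthest from the other tissues, with medians from 0.470 against root to 0.603 against early female flower. Some libraries lay apart from their own group. Leaf replicate 1 correlated at a mean of 0.762 with the other leaf libraries and at 0.849 with the early female libraries, and root replicate 2 correlated at 0.815 with the other roots and at 0.791 with the leaf libraries.

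**Figure D1:**
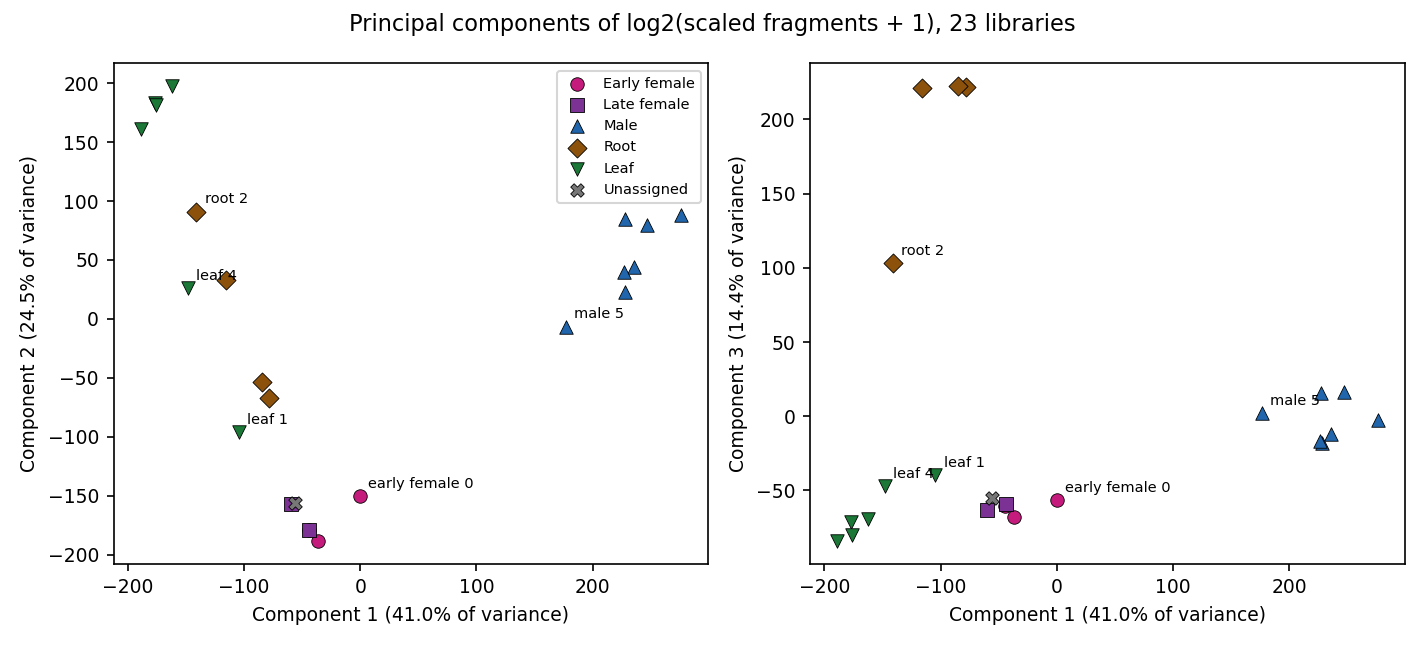
Principal components 1 against 2 and 1 against 3 of log2(scaled fragments + 1) for all 23 libraries, with the share of variance (in percent) on each axis and 1 point per library coloured by group. Male libraries lie apart along component 1, which held 41.0% of the variance, while leaf replicates 1 and 4, root replicate 2 and male replicate 5 lie away from the rest of their groups.

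Male flower held a larger share of its scaled fragments in genes enriched in it than the other 3 tissues did. The range of root overlapped those of leaf and female flower. The sets differed in size, and the shares were not tested against each other. A gene was counted as enriched when it was at least 4-fold above each of the other 3 tissues at an adjusted p under 0.05 in each contrast (limma, Benjamini-Hochberg adjustment). Male flower had 1962 such genes, root 868, leaf 603 and female flower 595. Measured with gene sets made without the library in question, male-enriched genes held 57.8% ± 8.99 (SD, n = 7) of all scaled fragments in male flower, against 4.70% ± 0.846 (n = 3) in early female flower, 3.77% ± 0.102 (n = 2) in late female flower, 4.16% ± 0.747 (n = 4) in root and 3.05% ± 0.537 (n = 6) in leaf. Leaf-enriched genes held 15.6% ± 5.14 (n = 6) of the fragments in leaf, and root-enriched genes held 8.74% ± 2.87 (n = 4) in root. Female-enriched genes held 5.27% ± 0.503 (n = 3) in early and 4.46% ± 0.236 (n = 2) in late female flower, and 0.183% ± 0.147 (n = 7) in male flower. The 10 most abundant genes of each set took 15.6% of the male-enriched fragments, 21.6% of the root-enriched, 26.4% of the leaf-enriched and 29.0% of the female-enriched ones. The number of female-enriched genes rested on single libraries, since it was 369 without late female replicate 1. Without leaf replicates 1 and 4, root replicate 2, early female replicate 0 and male replicate 5, a choice made after seeing the data, the number of leaf-enriched genes was 912.

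**Figure D2:**
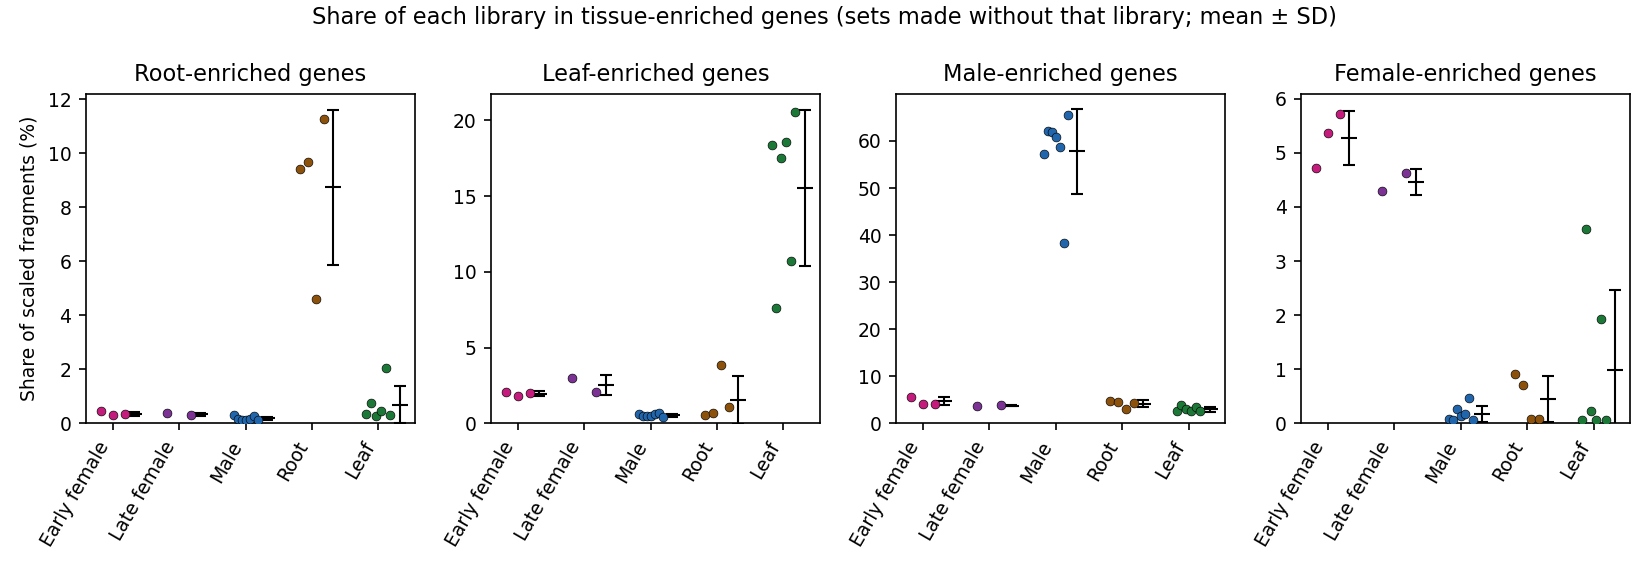
Share of scaled fragments (percent, vertical axis) in root-, leaf-, male- and female-enriched genes, 1 panel per gene set with its own scale, for each library of the 5 groups; points are libraries and the bar beside them is the mean ± SD. Male-enriched genes take 38.3% to 65.5% of the fragments in the 7 male libraries and at most 5.68% in any female library.

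Root and leaf, the below-ground and above-ground vegetative tissues, were compared first. Of 17423 genes tested, 3058 were higher in root and 1952 were higher in leaf, together 28.8% of the genes, with a median absolute log2 fold change of 2.83. Zosma49g00020 stood at 1406 ± 159 scaled fragments in root (SD, n = 4) and at 0.602 ± 0.50 in leaf (n = 6), where 4 fragments were counted over all 6 libraries. Zosma152g00070 showed the opposite, with 23620 ± 15589 in leaf and 31.5 ± 8.76 in root. At least 16-fold differences were found for 938 genes higher in root and 517 higher in leaf.

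The log2 fold change of Zosma49g00020 between root and leaf was 9.84 (SE 0.621, adjusted p = 3.89e-10, limma with Benjamini-Hochberg adjustment), and that of Zosma283g00030, at 1616 ± 688 in root and 1.22 ± 0.799 in leaf, was 9.46 (SE 0.700, adjusted p = 3.04e-09, limma). In the direction of leaf, limma gave Zosma152g00070 a log2 fold change of -9.23 (SE 0.542, adjusted p = 2.02e-10). Zosma10g01450, at 5.65 ± 3.43 in root and 3906 ± 3894 in leaf, had -9.04 (SE 0.782, adjusted p = 2.37e-08, limma). Root replicate 2 held 3.87% of its fragments in leaf-enriched genes, against 0.576% to 1.07% in the other roots, and leaf replicate 4 held 2.05% in root-enriched genes, against 0.292% to 0.757% in the other leaf libraries. Without root replicate 2 and leaf replicates 1 and 4, a choice made after seeing the data, 7978 genes differed, 5294 of them higher in root, and with estimated library weights 9697 differed. Under quantile normalization the split was 2404 higher and 2422 lower.

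Female flower was compared with leaf as the mean of its early and late time points. Female flower had 4671 genes above leaf and 3325 below it, 45.9% of those tested, with a median absolute log2 fold change of 2.56. Zosma48g00740 rose from 9.17 ± 19.5 scaled fragments in leaf (SD, n = 6) to 6214 ± 5473 in early (n = 3) and 13934 ± 3652 in late female flower (n = 2). Zosma92g00250 rose from 3.26 ± 4.34 in leaf to 3845 ± 956 in early and 11490 ± 728 in late female flower. In the other direction, Zosma366g00170 was at 0 in all 5 female libraries and at 906 to 42983 in the 6 leaf libraries, a difference of at least 4981-fold against a floor of 3 fragments per library. That limit rested on leaf replicate 2 and was 1564-fold without it. Zosma470g00020 stood at 5024 ± 3441 in leaf, 2.26 ± 2.12 in early female flower and 0 in both late libraries.

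In the limma test of female flower against leaf the log2 fold change of Zosma48g00740 was 11.46 (SE 1.41, adjusted p = 4.78e-06) and that of Zosma92g00250 was 11.15 (SE 0.960, adjusted p = 1.18e-07), with Benjamini-Hochberg adjustment. The limma value for Zosma366g00170 was -11.89 (SE 0.897, adjusted p = 2.75e-08), which depends on the pseudocount because of the zeros. For Zosma470g00020 it was -10.99 (SE 0.769, adjusted p = 9.57e-09, limma). Leaf replicate 1 held 3.59% of its fragments in female-enriched genes and leaf replicate 4 held 1.93%, against 0.0551% to 0.232% in the other leaf libraries. The split depended on the scaling: with libraries scaled to equal total fragments, an alternative chosen after seeing the data, 6034 genes were higher and 2291 lower in female flower, and the median log2 fold change of all genes moved from 0.10 to 0.55, while quantile normalization gave 3986 higher and 3709 lower.

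More genes were called between male flower and leaf than between leaf and either female flower or root. Of the 17423 genes, 5519 were higher and 4264 lower in male flower, 56.1% of those tested, and 1857 were at least 16-fold higher. Zosma97g00770 was at 76705 ± 29671 scaled fragments in male flower (SD, n = 7) and 25.9 ± 20.7 in leaf (n = 6). Zosma114g00930 was at 23136 ± 13194 in male flower and 6.78 ± 5.93 in leaf. Among genes lower in male flower, Zosma17g01050 went from 7104 ± 7400 in leaf to 7.69 ± 12.7, and Zosma252g00240 from 2520 ± 1731 to 3.55 ± 6.62.

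The limma log2 fold changes of Zosma97g00770 and Zosma114g00930 between male flower and leaf were 11.65 (SE 0.677, adjusted p = 1.69e-11) and 11.63 (SE 0.649, adjusted p = 1.02e-11), with Benjamini-Hochberg adjustment. By the same limma test Zosma17g01050 had -9.87 (SE 1.09, adjusted p = 1.41e-07), with a value in leaf replicate 1 far below the other leaf libraries, and Zosma252g00240 had -9.55 (SE 1.15, adjusted p = 4.49e-07). Male replicate 5 held 38.3% of its fragments in male-enriched genes, against 57.2% to 65.5% in the other 6 male libraries. The balance of directions turned with the scaling: with libraries scaled to equal total fragments, chosen after seeing the data, 4000 genes were higher and 5927 lower in male flower, and the median log2 fold change of all genes moved from 0.19 to -0.37. Quantile normalization gave 4505 higher and 5123 lower.

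Genes that moved away from leaf in the same direction in flowers of both sexes were counted as well. There were 2432 genes higher than leaf in both and 2213 lower in both, where lists drawn independently would share 1480 and 814. The flowers were compared with the same leaf libraries, which adds to such an overlap. In 20 simulations all libraries, leaf included, were drawn without any tissue effect, and at most 1 gene was called per comparison. Their overlap of 0 called genes says nothing about lists of this length. Lists of the observed lengths, taken from the top of the same simulations, shared 2553 to 2664 genes in the higher and 1625 to 1733 in the lower direction. With the deposited scaling, the only one run here, the observed overlap lay below that range for higher genes and above it for lower genes. No gene had an effect in those simulations, unlike the many genes called here. They therefore cannot tell how much of the observed overlap comes from the shared leaf libraries. The leaf libraries were also divided into 3 for each sex, in all 20 possible divisions. Then 1724 to 2077 genes were higher in both and 1605 to 1982 were lower in both, against a median independent expectation of 1237 and 669.

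In the reported fit, nearly as many genes were called between the flowers of opposite sexes as between male flower and leaf. The order turned with only the compared groups fitted, at 9466 and 9279 genes, and with equal total fragments, at 11011 and 9927. In the reported fit, 4537 genes were higher in male flower and 4557 higher in female flower, 52.2% of the genes tested. The median absolute log2 fold change between the sexes was 2.53. Zosma271g00020 stood at 25027 ± 19618 scaled fragments in male flower (SD, n = 7), 9.90 ± 1.82 in early (n = 3) and 4.88 ± 0.293 in late female flower (n = 2). Zosma117g00850 stood at 12066 ± 5285 in male flower, 7.65 ± 4.24 in early and 3.15 ± 0.681 in late female flower. On the female side, Zosma291g00120 was at 3938 ± 1678 in early and 6355 ± 961 in late female flower and at 32.1 ± 53.6 in male flower. Zosma122g00160 was at 1310 ± 338, 2406 ± 1115 and 20.1 ± 38.2 in the same groups. In leaf (n = 6), Zosma122g00160 was at 2077 ± 2560, from 0 to 6011. Zosma291g00120 was at 4819 in leaf replicate 1 and at 0 to 2.70 in the other leaf libraries.

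Between male and female flower limma gave log2 fold changes of 10.85 for Zosma271g00020 (SE 0.788, adjusted p = 7.57e-10) and 10.84 for Zosma117g00850 (SE 0.529, adjusted p = 1.09e-11), with Benjamini-Hochberg adjustment. On the female side limma gave -9.01 for Zosma291g00120 (SE 1.66, adjusted p = 1.12e-04) and -9.02 for Zosma122g00160 (SE 2.15, adjusted p = 0.00131). Early female replicate 0 held 5.68% of its fragments in male-enriched genes, against 3.70% to 4.21% in the other 4 female libraries. The split depended on the scaling. Deposited values summed to 10845975 to 25737103 per male library and to 6869880 to 7687605 per early or late female library. With libraries scaled to equal total fragments, chosen after seeing the data, 2600 genes were higher and 8411 lower in male flower, and the median log2 fold change of all genes moved from -0.03 to -1.15, while the genes named here kept their direction and passed the test.

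In the reported fit, which shares its spread over all 5 groups, few genes were called between early and late female flower. Of the genes tested, 5 were higher and 8 lower at the late time point, 0.0746%. An unadjusted limma p under 0.05 was found for 764, fewer than chance alone gives at that cutoff. Correlations within groups went down to 0.703 in leaf, 0.769 in root and 0.759 in male flower, against 0.942 in early female flower. More genes were called from the female libraries alone, so the small number does not show that the stages barely differ. The direction turned with settings, at 33 higher and 24 lower with a pseudocount of 10 but 3 and 5 with a filter at 50. The 13 genes called in the reported fit moved far, with a median absolute log2 fold change of 5.54. Zosma95g00370 rose from 10.6 ± 7.61 scaled fragments at the early (SD, n = 3) to 1112 ± 648 at the late time point (n = 2). Zosma249g00020 was at 0 in all 3 early libraries and at 104 ± 22.3 in the late ones, at least 55.9-fold higher against a floor of 3 fragments per library. Zosma22g01000 fell from 999.8 ± 179 to 1.09 ± 1.54, where 3 fragments were counted, all in late replicate 1, a ratio of 918 with a counting interval from 314 to 4452. Without late replicate 0 the ratio was 459, with an interval from 157 to 2226, and without late replicate 1 the fall was at least 499.8-fold. Zosma25g00360 fell from 441 ± 291 to 1.42 ± 1.07.

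The limma log2 fold changes between late and early female flower were 6.81 for Zosma95g00370 (SE 0.865, adjusted p = 5.09e-04), 6.69 for Zosma249g00020 (SE 0.842, adjusted p = 5.09e-04), -9.12 for Zosma22g01000 (SE 0.921, adjusted p = 3.00e-05) and -7.21 for Zosma25g00360 (SE 1.34, adjusted p = 0.0417), with Benjamini-Hochberg adjustment. The call of Zosma25g00360 was lost with a pseudocount of 0.1, with a filter at 50 and without early replicate 0, early replicate 1, late replicate 0 or late replicate 1, that of Zosma95g00370 with a pseudocount of 0.1 and without late replicate 1, and that of Zosma249g00020 with a pseudocount of 0.1. With zeros in the early libraries, the log2 fold change of Zosma249g00020 depended on the pseudocount, at 10.00 with 0.1 and 3.49 with 10, and it was not tested without late replicate 0 or without late replicate 1, where it did not pass the filter. The number of calls depended on the settings and on single libraries: limma called 4 genes without late replicate 1 and 5 without late replicate 0, 465 when only the female libraries were fitted and 42 (21 higher, 21 lower) after quantile normalization. With the library of conflicting labels counted as early, limma called 0 genes (350 at an unadjusted p under 0.05, fewer than chance gives), and with it counted as late, 43 genes.

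**Figure D3:**
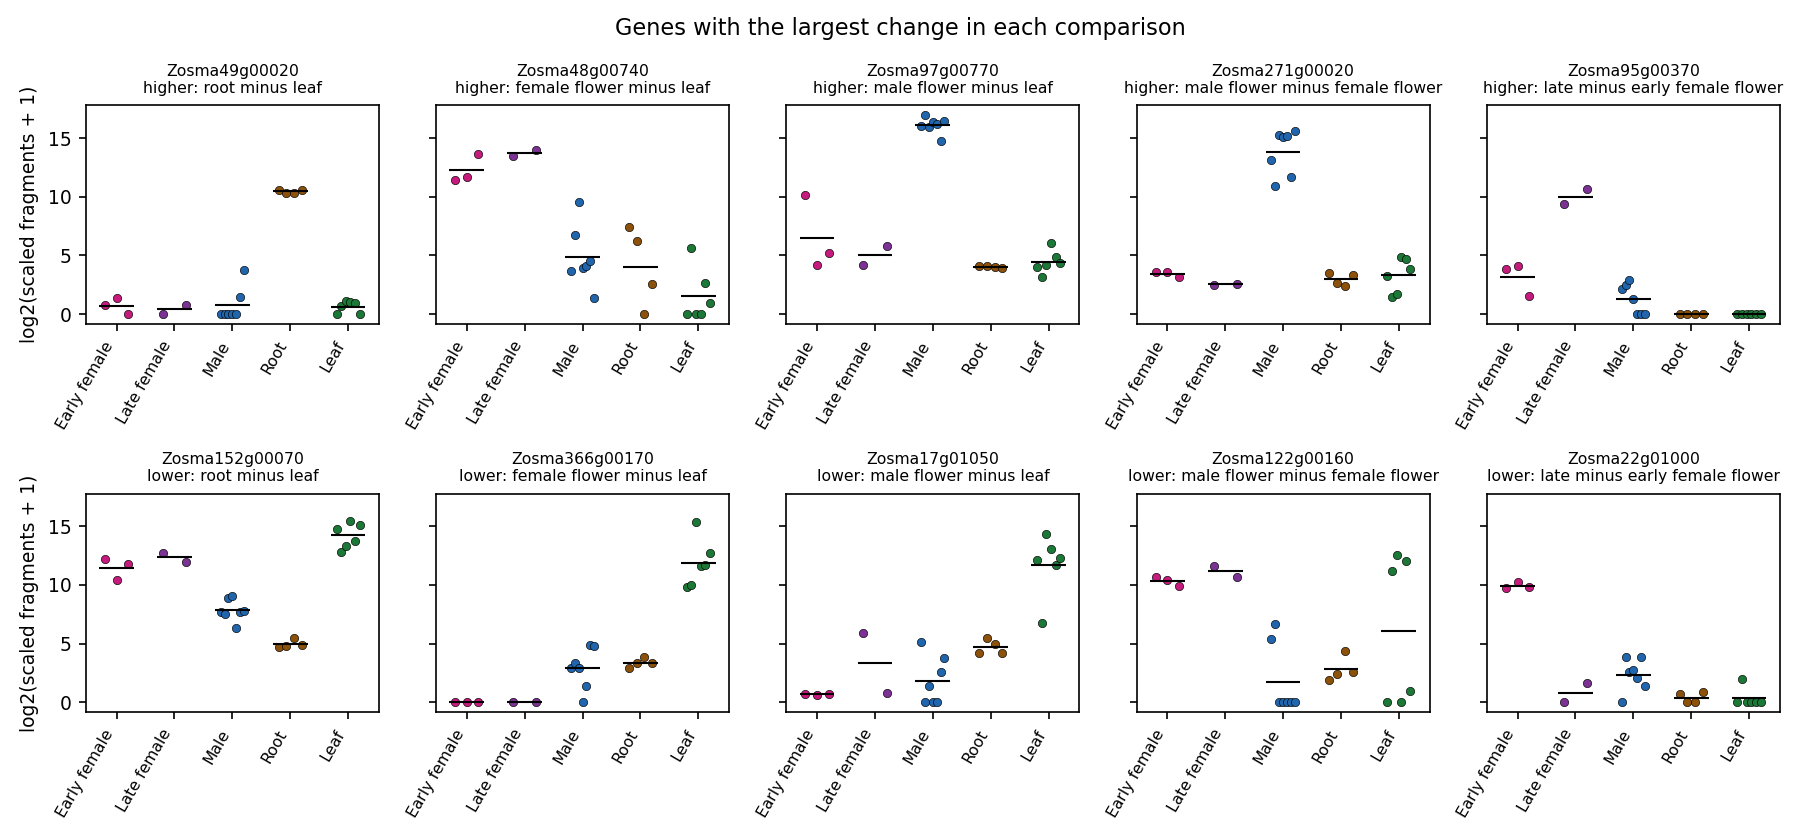
Log2(scaled fragments + 1) of each library (vertical axis) in the 5 groups for the gene with the largest fold in each direction of each comparison; points are libraries and lines are group means. In each panel all libraries of 1 compared group lie above all libraries of the other, as the rule for naming genes required.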

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

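The tests of whether an admixture accounts for a library's share in its own tissue's genes, for the levels of those genes and for every abundant gene of the other tissue were chosen only after the result was seen, while the other tests in this part were set out beforehand. Of 62 groups of values examined for a sample far from the rest, 9 had one, and chance alone gives about 1 in 20.

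Leaf replicate 1 correlated at a mean of 0.762 with the other leaf libraries, which had means from 0.851 to 0.889, and its log2 value of the leaf gene Zosma17g01050 was 6.73 against 11.72 to 14.37 in the other 5. Against a female flower library under a leaf label stands its share of 7.61% in leaf-enriched genes, where the female libraries held 1.81% to 2.99%. Admixture of flowers like those sampled stays open for its female genes. In this library 200 abundant female-enriched genes stood at a median of 40.6% of their female level. Of them 16.5% lay over 4-fold below that median, under the limit of 25% set for a mixture. Female libraries left out the same way gave 4.24% to 9.38%, all lower, but too high for that limit to count against a mixture. Over 16-fold below it lay 9.0%, against 1.23% to 6.25% in those female libraries, above them by less than their own range. Such an admixture may account for the share in leaf-enriched genes, which it puts at 4.33% to 17.5%. This range is wide, since it used the quartiles of the fractions, 17.54% and 71.72%, with the highest and lowest other leaf library. Its low end rests on leaf replicate 4, at 10.7%, which itself lay apart, so the range cannot decide. Such an admixture does not account for 18.6% of 586 abundant leaf-enriched genes. These lay below the level that dilution leaves of the lowest other leaf library. Each other leaf library, compared with the rest without leaf replicate 1, gave 0 to 7.91%. A flower of another stage and a leaf that itself expressed these genes stay open and were not tested.

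Root replicate 2 held 3.87% of its fragments in leaf-enriched genes, against 0.576% to 1.07% in the other roots. A leaf library under a root label is argued against by its 4.61% in root-enriched genes, where leaf libraries held 0.292% to 2.05%. Admixture of leaf may account for many of the leaf genes but not for all. Of 284 abundant leaf-enriched genes, 24.3% lay over 4-fold below the common fraction of 4.13%, close to the limit of 25%. Leaf libraries left out the same way gave 4.43% to 14.6%, again too high for that limit to count against an admixture. Over 16-fold below that fraction lay 8.45%, against 1.10% to 3.18% in those leaf libraries. Admixture does not account for the low root genes, since it predicts at least 8.37% in root-enriched genes against the 4.61% observed. Of 425 abundant root-enriched genes, 83.5% lay below the level that dilution leaves. The other roots, compared without root replicate 2, gave 22.4% to 29.0%. In root replicate 2, 44 genes with at least 100 fragments in each of the other 3 roots were at 0. A difference in the part or age of the root stays open and was not tested.

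Early female replicate 0 held 5.68% of its fragments in male-enriched genes, against 3.70% to 4.21% in the other female libraries, a difference singled out from the values. A male library under a female label is argued against by its 4.73% in female-enriched genes, where male libraries held 0.0594% to 0.469%. A small admixture of male flower may be the source: 800 abundant male-enriched genes stood at a common fraction of 1.5% of their male level, against 0.231% to 0.309% in the other female libraries, with 10.4% of them over 4-fold and 4.5% over 16-fold below it, within the range of male libraries left out the same way. Such an admixture would leave at least 4.18% in female-enriched genes, below the 4.73% observed, and 30.2% of 159 abundant female-enriched genes lay below the level that dilution leaves, within the 8.74% to 42% of the other female libraries compared without it. Male libraries had larger sums of scaled fragments, 10845975 to 25737103 against 7313732 in early female replicate 0, so the 4.18% is somewhat too high. Male genes active in the young female flower of this sample were not tested as an alternative.

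Male replicate 5 held 38.3% of its fragments in male-enriched genes, against 57.2% to 65.5% in the other male libraries. It held 0.0937% in identifiers beginning with ZosmaC, against 0.00271% to 0.0120%. Its share in identifiers beginning with ZosmaM was 0.207%, against 0.00586% to 0.0384%. Male replicate 1, the library of lowest depth, had 13878 genes with at least 3 fragments, against 15423 to 15825. Its log2 value of Zosma117g00850 was 11.30, against 13.35 to 14.28. Leaf replicate 4 held 2.05% of its fragments in root-enriched genes, against 0.292% to 0.757% in the other leaf libraries.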

How the results depend on the processing

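Scaling to equal total fragments and leaving out the libraries that lay apart were chosen after seeing the data. Over these and the settings fixed beforehand, 107 counts of changed genes stayed within 1.5 times the reported one, 9 were higher and 5 lower. Of the values of named genes, 467 kept their direction and passed the test, 15 kept their direction but not the test, all of them for late against early female flower, and none was reversed. The calls between late and early female flower, 13 as reported, numbered 5 with a pseudocount of 0.1, 57 with a pseudocount of 10, 38 without a filter, 8 with a filter at 50, 48 from FPKM, 42 with quantile normalization, 1299 with library weights and 465 from the female libraries alone. With the unassigned library as early they numbered 0, and with it as late 43. As early, 350 genes had an unadjusted p under 0.05 in limma, fewer than chance gives. Leaving out 1 library gave 4 (late replicate 1) to 12 calls, and 5 without late replicate 0, where the lone late library is assumed to vary like the other groups. Root against leaf gave 9697 calls with library weights, whose estimation did not fully converge, and 7978 without root replicate 2 and leaf replicates 1 and 4. A fit of the female libraries alone also leaves out the spread of the other tissues. Apart from that and the smaller number of genes tested or of libraries, the cause was not tested.

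Leaf-enriched genes numbered 1070 at 2-fold, 254 at 8-fold and 912 without the 5 libraries that lay apart. Female-enriched genes numbered 342 at 8-fold, 968 with equal total fragments, and 369 (without late replicate 1) to 771 (without leaf replicate 1) with 1 library left out. Leaving out 1 library gave 3862 to 6531 calls for root against leaf, 6844 to 8888 for female flower against leaf, 9493 to 10229 for male flower against leaf and 8178 to 9360 for male against female flower.

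The replicate numbers were not shown to pair the samples: in no pair of groups sharing 3 or more numbers did all same-numbered libraries deviate together. Groups sharing 2 numbers were not judged. Among these, the deviations of same-numbered libraries correlated at 0.111 and 0.167 for early and late female flower, and at 0.168 and 0.191 for late female flower and leaf. They correlated at 0.001 and 0.190 for late female and male flower, and at -0.174 and 0.155 for late female flower and root. A pairing in such groups stays open. With the number as a block, the calls were 4614, 7169, 9605, 8430 and 11 in the order of the report, the call of Zosma25g00360 was among those lost, and female-enriched genes fell to 370. The count-based tests and the tests of named gene lists were not run.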

Other observations

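The tests of identifier groups below were chosen after the files were seen, and the tests of consecutive identifiers were set out beforehand.

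Genes with the identifier prefixes ZosmaC and ZosmaM, which the files do not explain, were tested as 2 groups in the 5 comparisons. Of these 10 tests, 8 passed by camera with a preset correlation, 3 by fry and 0 by camera with an estimated correlation. Of 32 ZosmaC genes, 19 were lower and 0 higher in root than in leaf by limma, with a median log2 fold change of -2.56 (camera adjusted p = 7.37e-11, fry adjusted p = 0.00243, camera adjusted p = 0.754 with an estimated correlation). In male against female flower 26 were lower and 1 higher, with a median of -2.36 (camera adjusted p = 4.76e-04, fry adjusted p = 0.0315, camera adjusted p = 0.754 with an estimated correlation). Of 38 ZosmaM genes, 20 were higher and 0 lower in female flower than in leaf by limma, with a median of 2.24 (camera adjusted p = 3.06e-04, fry adjusted p = 0.0421, camera adjusted p = 0.754 with an estimated correlation). The other 7 tests had fry adjusted p from 0.0776 to 0.553. The libraries were selected for polyadenylated RNA, and shares of fragments in these genes varied between female libraries. In ZosmaC genes early replicates 0, 1 and 2 held 0.0358%, 0.140% and 0.206%, late replicates 0 and 1 held 0.0541% and 0.644%, and the unassigned library held 0.541%. In ZosmaM genes the same libraries held 0.0142%, 0.0420%, 0.0990%, 0.0201%, 0.418% and 0.361%, against 0.00791% to 0.0433% in the leaf libraries.

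Tissue-enriched genes often carried consecutive identifiers. There were 454 pairs of consecutive identifiers enriched in the same tissue, where 10000 random sets of the same sizes among the tested identifiers gave 202 to 317, so chance placement is argued against. Root-enriched genes formed 104 such pairs against a mean of 36.6 over 500 further random sets, leaf-enriched 42 against 17.7, male-enriched 276 against 186 and female-enriched 32 against 17.1. The longest runs were 10 male-enriched genes from Zosma194g00290 and 6 root-enriched genes from Zosma29g00210, chosen after their values were seen. A candidate explanation is fragments divided between neighbouring copies of a gene, but values that were not whole multiples of the step were only 1.78 times as frequent in genes of such pairs (0.102% against 0.0574%), below the 2 times set beforehand as the bound against it. Fragments counted in full at each copy would stay whole and remain open, as does a shared activity of neighbouring genes. Both are hypotheses, and positions of genes were not analysed here.

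The library whose title says early and whose tissue label says late correlated across genes at a mean of 0.930 with the 3 early libraries (0.917 to 0.941) and 0.974 with the 2 late ones (0.972 to 0.975). It held 5.55% of its fragments in female-enriched, 3.91% in male-enriched, 2.83% in leaf-enriched and 0.492% in root-enriched genes. Zosma249g00020, named for late against early female flower, was at 93.7 scaled fragments in it, against 0 in the early and 87.9 to 119 in the late libraries. Zosma95g00370 was at 673, against 1.95 to 16.2 and 653 to 1570. Zosma22g01000 was at 2.34, against 867 to 1203 and 0 to 2.18. Zosma25g00360 was at 2.34, against 107 to 642 and 0.667 to 2.18. Its chi-square per degree of freedom was 30.3 and 40.3 against the late libraries and 119 to 135 against the early ones. By these values it resembled the late libraries more than the early ones.

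Other groupings of the libraries were drawn to see how often they called as many genes as the labels, in 100 splits that include the real one. For root against leaf 2 of 100 did, with 5010 genes by the labels and 6547 in the highest other split, which exchanged root replicate 2 and leaf replicate 1. For female flower against leaf, male flower against leaf and male against female flower 1 of 100 did, the real one, with 7996, 9783 and 9094 genes against at most 6696, 5856 and 5760 in the others. In each of the 4 comparisons fewer than 5 of 100 splits called as many genes. The other splits called a median of 0 genes in each, since splits that mix tissues add the tissue difference to the spread. Few such splits were therefore likely beforehand, and the replicates may not be separate plants. No conclusion on chance is drawn from this test. Late against early female flower, with 2 late libraries, was not tested in this way.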
